A study of Mus musculus with 14 samples.

How the data were processed

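Single cells of 14 mouse samples were read by Smart-seq2, with 539 cells from 9 tumor-bearing samples and 109 from 5 control samples. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to mm10 with HISAT2 and assigned to genes with featureCounts, with SAMtools, and the matched DNA reads were handled with BWA and Picard. Tool versions are not given in the sources used here. The deposited values are raw counts per gene and cell, 21138 genes by 648 cells, whole numbers with no normalization. The DNA and SNP data were not analysed here. Gene symbols were matched to GENCODE vM21 (GRCm38), which held 18884 of them, 18805 as protein-coding genes, and coordinates come from that annotation.

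Values of 2 outnumbered values of 1 by 3.59 times and 56.7% of nonzero values were even, so a count may not be a single fragment, and reads copied by PCR were not marked. Intervals and floors therefore cover counting error only. Counts per cell ranged from 20525 to 104170496. All 648 cells passed a minimum of 10000 counts and 500 detected genes, 1 failed a stricter minimum of 100000 counts and 1000 genes, and 888 genes had no count. Depth set the precision unevenly, since the sums for DP, CTC and WBC held 7317, 1138 and 348 Mcounts (megacounts), so 0 counts in naive WBC, with 26.6 Mcounts, bounds a gene less tightly than 0 counts in CTC.

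The sample, which is the batch label, was the unit of replication. The labels do not say whether samples are separate animals, so p-values may measure technical spread. Counts were summed per sample, tissue and class over at least 2 cells, which gave 30 sums for the classes. CPM values of comparisons are TMM-scaled, averaged over the tissues of a sample and then over samples. Tests used edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) with limma 3.58.1 in R 4.3.3, with the sample as a replicate block and tissue as a term, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Classes were paired by sample because they were sorted from the same samples. The pairing was checked on 7386 genes: the median correlation was 0.0301 over 41 pairs of classes of the same sample (-0.0671 to 0.249, 5 over 0.1) and -0.0042 over 246 pairs of different samples (-0.248 to 0.160). No pair of cells had identical counts.

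Gene lists were 29 in number, with 368 genes, 9 of them without values, and 26 were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Counts of members are given over all genes and adjusted over the list alone. Shares of counts, detection of both programmes and melanoma-like shares were compared by exact two-sided sign-flip permutation tests within samples, and proportions of cells have exact binomial intervals. Where a group had 0 counts, a floor of 3 counts over the whole group gave the least fold.

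Cells were clustered on log2 CPM of 2000 variable genes, reduced to 15 principal components (the first held 39.6% of the variance and the next 3.66%), by Ward linkage into 10 clusters and 2 branches. The branch with the higher mean of the melanocyte list was called melanoma-like. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used. No doublet caller was run.

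Genes were named by rule: in each tested comparison the 12 largest differences in each direction among protein-coding genes past the threshold, with a mean of at least 20 CPM and the same sign in every sample that held both classes, the 5 with the smallest p where fewer than 5 passed, a fixed set of key genes, and up to 4 examples per list. Results of a few genes that the rule named are not reported here. For lone controls the 5 largest in each direction were taken without the condition on signs. The comparisons, gene lists, naming rule, thresholds and a set of alternatives were fixed before the data were examined. Chosen after seeing the data were the comparisons within the melanoma-like and the other branch, the melanoma-like share of lung and blood, the pan-leukocyte share, the differences of lung against blood between classes, and the alternatives in lung cells or melanoma-like cells alone. Alternatives covered scaling, filters, DESeq2 1.42.0, the block, cell weights, cells per sum, tissue, thinning, clustering settings and each sample left out.

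The steps were tested on simulated data with changes of log2 2 and log2 6 in either direction. Recovered at each size were 9% and 77% of changed genes for DP and WBC, 4.33% and 73.7% for DP and CTC, and 2% and 71% for CTC and WBC, each on 12595 genes. For lung and blood the shares were 3% and 59.6% (12306 genes), for melanoma-like cells 52% and 86% (11856), and for the other branch 0% and 56.7% (9834). For the lone controls they were 0% and 31% for CDP, 0% and 27% for B16F10 and 1% and 21% for naive WBC (16423 each), and for the differences of lung against blood 0% and 19% for DP and WBC and 0% and 4% for DP and CTC. Of the genes called, from 0% to 5.19% were unchanged ones. A count of 0 genes therefore leaves changes of log2 2 open. Apart from library size and the changes, each simulated gene had the same mean in every sum, with the spread taken from the fit. Effects of sample and the mixture of branches were not simulated, so errors and recovery in the real sums may differ.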

Results

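RNA was read from 648 single mouse cells of 14 samples with Smart-seq2, a plate-based method that makes 1 full-length library per cell. In 9 samples, female C57BL/6J mice aged 6 to 8 weeks had received fluorescently labelled B16F10 cells, a melanoma line of the same strain. Their blood and lung cells were sorted into classes that the labels name CTC, DP and WBC, and the series title describes the cells of interest as candidate hybrids of tumor cells and leukocytes. The 539 cells of these samples comprised 450 DP cells from 9 samples, 46 WBC from 6 samples and 43 CTC from 5 samples. The 5 controls had 1 sample each, with 22 B16F10 cells, whose labels give the cell type CTC, 21 WBC, 24 Duplike, 24 PltLike and 18 CDP cells, and the labels give the last 4 the treatment naive. Total counts in replicates 1 to 9 were 767, 851, 1121, 208, 1449, 1513, 1728, 611 and 565 Mcounts (megacounts), and the controls ranged from 26.6 Mcounts in naive WBC to 471 Mcounts in PltLike. The median cell had 15.8 Mcounts, with medians of 22.1 in CTC, 15.8 in DP, 4.93 in WBC and 1.05 Mcounts in naive WBC. The sort used tumor and host markers that the labels do not name. Ptprc encodes the leukocyte antigen CD45, a common sort marker, so class differences in such genes were not independent of the sort.

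The DP class held cells of both a melanoma-like and a leukocyte-like transcriptome. Clustering of all cells gave a melanoma-like branch of 402 cells and another branch of 246 cells. All 22 B16F10 cells and 42 of 43 CTC lay in the melanoma-like branch, and all 46 WBC and 21 naive WBC lay in the other. Among DP cells, 200 of 273 from blood were melanoma-like (73.3%, exact 95% binomial interval 67.6 to 78.4), against 72 of 177 from lung (40.7%, 33.4 to 48.3). In the 5 samples with DP cells from both tissues the share averaged 19.1% ± 30.9 (SD) in lung and 73.0% ± 31.6 in blood. It was lower in lung in 4 of 5 samples, with a mean difference of -54.0 points (exact sign-flip permutation p = 0.125, smallest possible 0.0625). Replicate 7 went the other way, and without it the mean difference was -79.6 points. Replicates 7 to 9, labelled P1, P2 and P4, held 72.3% and 91.4% in lung (replicates 7 and 8) and 23.9% and 44.8% in blood (7 and 9). Of these, replicate 7 alone held both tissues, so replicates 8 and 9 could not show a reversal. Replicates 1 to 6 held 0% to 20% in lung and 59.1% to 100% in blood, and the 2 sets of samples were not tested against each other. Clustering without the 50 genes that lead each branch moved 4 of 648 cells.

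Most DP cells of the other branch lay in leukocyte-like clusters. Of the DP cells in this branch, 42 from blood and 1 from lung lay in a monocyte and macrophage-like cluster with high C1qb, Lyz2 and Itgam. A second cluster of this kind, with C1qc and Pf4, held 25 from blood and 17 from lung, and one with Spp1 and Ccl4 held 1 and 26. An alveolar macrophage-like cluster, with Chil3, Atp6v0d2 and Plet1, held 48 DP cells from lung and 0 from blood. A B-cell-like cluster with Cd79a, Cd79b and Ms4a1 held 4 from blood and 0 from lung. The remaining cluster, whose leading genes included both fibroblast genes (Mgp, Col3a1) and neutrophil genes (S100a9, S100a8), was left unnamed and held 1 DP cell from blood and 13 from lung, 5 of them in replicate 1 and 8 in replicate 2. These counts describe where the cells lay and were not tested, because the genes that define the clusters differ between tissues. No doublet caller was run, and wells that received a pair of cells were not removed.

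**Figure D1:**
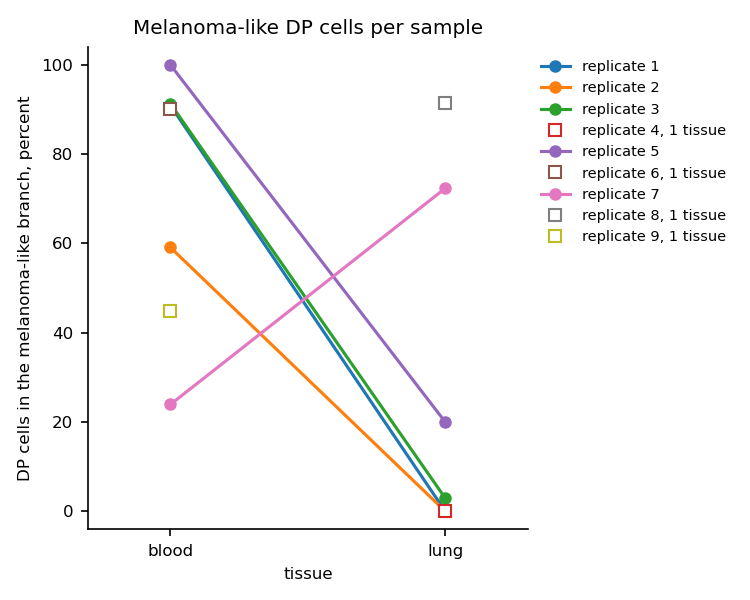
Percent of DP cells in the melanoma-like branch, in blood and in lung, for each tumor-bearing sample, with lines joining both tissues of a sample and open squares for samples with 1 tissue. The share is lower in lung in 4 of the 5 samples with both tissues, and higher in replicate 7 (72.3% against 23.9%).

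The comparison of DP with WBC asked how the DP class differed from leukocytes of the same samples. Melanocyte genes were far higher in DP. Tyrp1, which encodes a melanosomal enzyme (chromosome 4, 80834123 to 80851719), averaged 5543 ± 3497 CPM (SD, n = 9) in DP and 60.8 ± 96.7 (n = 6) in WBC, a log2 difference of 6.16 ± 0.76 (SE; adjusted p = 1.84e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and was higher in 6 of 6 samples. Pmel, the scaffold of melanosome fibrils (chromosome 10, 128704195 to 128720238), was higher by 6.02 ± 1.04 (adjusted p = 0.000506, 6 of 6 samples). Of 16 melanocyte genes, 14 were higher and 0 lower, with 15 higher when adjusted over the list alone, among them Slc45a2 (6.34 ± 1.01) and Trpm1 (5.88 ± 0.94). The list's median log2 difference was 5.87 (camera adjusted p = 0.000252, and adjusted p = 0.336 with an estimated correlation). Outside the list, Il17rc, an interleukin-17 receptor subunit, was higher by 8.87 ± 1.21 (adjusted p = 5.74e-05, 6 of 6 samples), and the metalloprotease gene Adam12 by 8.21 ± 1.25 (adjusted p = 0.000165, 6 of 6). Esam, an endothelial adhesion gene, had 0 counts in WBC and was at least 1922-fold higher in DP (a floor of 3 counts over all WBC).

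Leukocyte genes were lower in the DP sums than in WBC, but well above 0. These sums join unlike cells. In DP cells of the other branch the single-cell median of Ptprc was 327 CPM in blood and 238 CPM in lung. In melanoma-like DP cells it was 0.096 and 0 CPM. Ptprc (chromosome 1, 138062861 to 138175708) averaged 169 ± 182 CPM (n = 9) in DP and 751 ± 250 (n = 6) in WBC, and fell by 3.09 ± 0.81 on the log2 scale (adjusted p = 0.00903, lower in 6 of 6 samples). Of 16 pan-leukocyte genes, 11 were lower and 0 higher, with 15 lower when adjusted over the list alone, for example Cd37 (-4.15 ± 0.87) and Cd52 (-3.13 ± 0.68), at a list median of -3.16 (camera adjusted p = 1.73e-21, and adjusted p = 0.0253 with an estimated correlation). Among monocyte and macrophage genes 6 of 17 were lower (9 over the list alone), including C1qb (-3.61 ± 0.95) and Csf1r, the macrophage growth factor receptor (-3.31 ± 0.94), and the list passed at adjusted p = 5.2e-11 but not with an estimated correlation (adjusted p = 0.0599). Class II genes of the histocompatibility complex (MHC) were lower in 6 of 9 members (6 over the list alone), such as Cd74, the class II invariant chain (-3.84 ± 0.76), and H2-Eb1 (-4.40 ± 0.87), with a median of -3.51 (adjusted p = 5.82e-08, and 0.0731 as the adjusted p with an estimated correlation). Class I genes were lower in 5 of 11 (7 over the list alone), including B2m (-2.22 ± 0.45), and that list kept its call with an estimated correlation (adjusted p = 0.0253). The lymphocyte homing gene Ccr7 (-6.34 ± 1.65), the lipoxygenase gene Alox15 (-7.02 ± 1.58) and the chemokine gene Ccl24 (-6.77 ± 1.40) were among the largest decreases.

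Proliferation genes were higher in DP than in WBC for 9 of 19 members and lower for 0 (12 higher over the list alone), among them Mcm2, a replication helicase subunit (3.27 ± 0.82), and the cyclin gene Ccnb1 (5.19 ± 1.43), at a median of 3.27 (camera adjusted p = 0.000151, and adjusted p = 0.336 with an estimated correlation). Mki67, the common cycling marker, did not pass (1.84 ± 0.98, adjusted p = 0.195). Immediate-early genes were lower for 5 of 15 and higher for 1 (6 and 1 over the list alone), including Ier2 (-3.34 ± 0.66) and Junb (-3.22 ± 0.71), and this list kept its call with an estimated correlation (adjusted p = 0.0253). Of 11 immune checkpoint genes 3 were lower (5 over the list alone), such as Cd24a (-4.54 ± 0.81). Glycolysis and hypoxia genes were higher for 8 of 16 (9 over the list alone), for example Tpi1 (2.14 ± 0.45), but the list did not stand apart from other genes (median 1.72, camera adjusted p = 0.182). Mesenchymal genes went both ways, with Cdh2 higher by 7.23 ± 1.32, Sparc higher by 5.78 ± 1.34 and Fn1, which encodes fibronectin, lower by -4.51 ± 0.85, and Vim did not pass (-0.26 ± 0.29).

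Over all genes, 2586 of 12595 tested differed between DP and WBC, 2220 higher and 366 lower in DP. The median log2 difference of all genes was 1.17 with TMM scaling, 0.95 with DESeq2 size factors and 1.21 with TMMwsp. Without the replicate block it was 0.21, and 1980 genes were higher and 838 lower, so the shift and the low number of lower genes depended on the block. The count was 1599 without replicate 5, 294 with sums of at least 5 cells and 0 in lung cells alone, where 1473 genes had an unadjusted p under 0.05 and DESeq2 was not run. Of the 95 named genes that passed, 26 lost their call without replicate 5 and 14 to 16 without replicate 1, 2 or 3, among them Ptprc, C1qb, Csf1r and Ccnb1. The DP class held 60.4% melanoma-like cells.

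**Figure D2:**
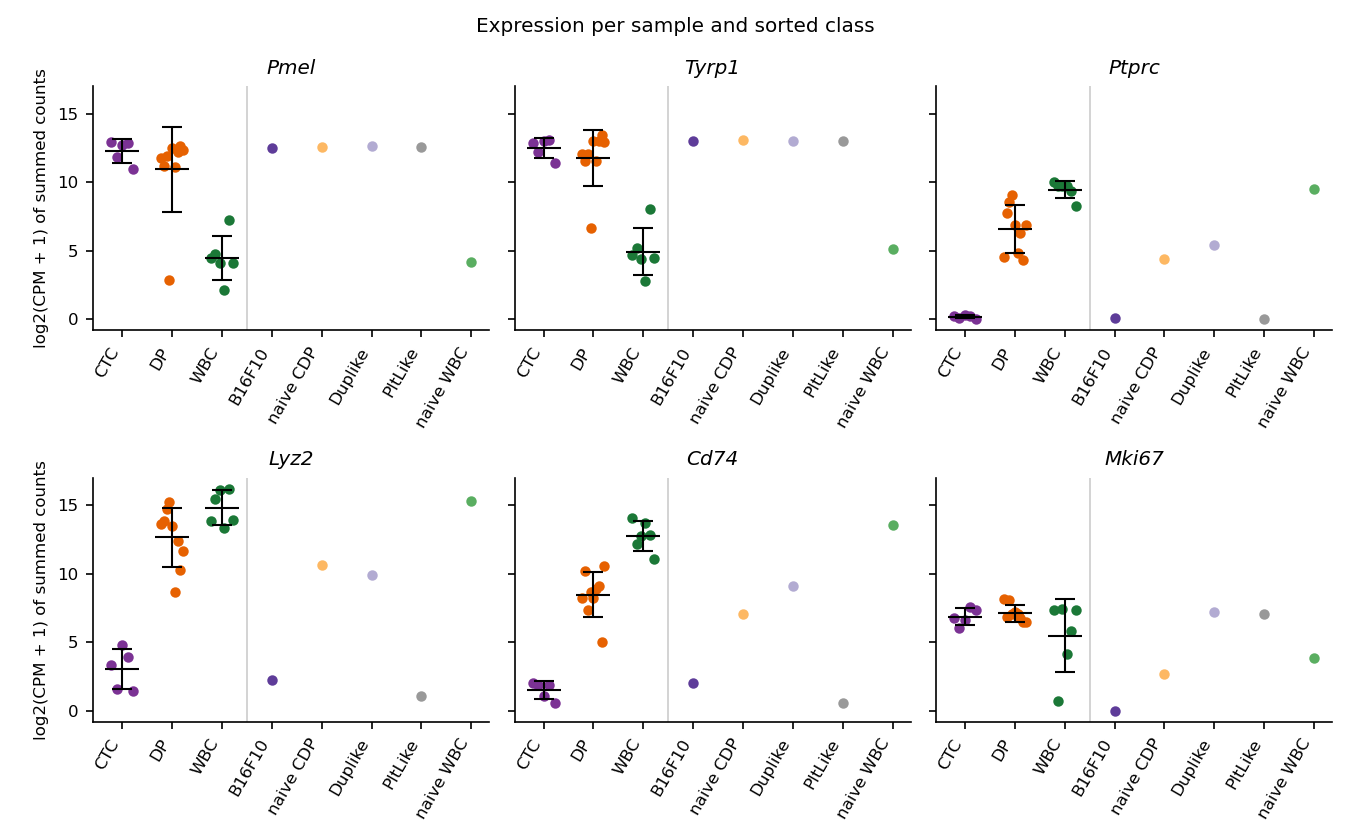
Expression of Pmel, Tyrp1, Ptprc, Lyz2, Cd74 and Mki67 as log2(CPM + 1) of summed counts, 1 point per sample, with mean and SD for CTC, DP and WBC and the 5 controls on the right of each panel. Ptprc lies at 169 ± 182 CPM in DP, between 0.141 ± 0.094 in CTC and 751 ± 250 in WBC. The DP sums join melanoma-like cells (single-cell medians of 0.096 CPM in blood and 0 CPM in lung) and cells of the other branch (327 and 238 CPM).

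The comparison of DP with CTC asked what set DP cells apart from the CTC of the same samples. All 737 genes that passed, of 12595 tested, were higher in DP, and leukocyte genes were prominent among them. Ptprc was higher by 9.40 ± 1.08 on the log2 scale (169 ± 182 CPM, n = 9, against 0.141 ± 0.094, n = 5, adjusted p = 4.51e-06 by edgeR's quasi-likelihood test) in 5 of 5 samples. Of 16 pan-leukocyte genes 14 were higher (14 over the list alone), for example Cd52 (9.36 ± 0.96), Cd53 (9.43 ± 1.08) and Laptm5 (8.97 ± 1.08), at a median of 8.61 (camera adjusted p = 1.53e-35, and adjusted p = 0.00112 with an estimated correlation). Monocyte and macrophage genes were higher for 15 of 17 (16 over the list alone), including Lyz2, which encodes lysozyme (8.92 ± 1.27), Csf1r (9.21 ± 1.18) and the complement gene C1qb (9.04 ± 1.18), and the list kept its call with an estimated correlation (adjusted p = 0.00112). Class II MHC genes were higher for 8 of 9 (9 over the list alone), with Cd74 (chromosome 18, 60803848 to 60812652) at 8.36 ± 1.08 and H2-Ab1 at 9.20 ± 1.11 (adjusted p = 0.00675 for the list with an estimated correlation). Class I MHC genes were higher for 4 of 11 (8 over the list alone), with a smaller median of 2.41 (adjusted p = 0.0433 with an estimated correlation).

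Other leukocyte lists had fewer members past between DP and CTC. Dendritic cell genes were higher for 5 of 8 (5 over the list alone), led by Itgax, the integrin CD11c (12.49 ± 1.92, adjusted p = 0.000117, 5 of 5 samples), with a median of 8.11, or 7.05 with Xcr1, at 0 counts in CTC, set at its bound. Platelet and megakaryocyte genes were higher for 4 of 9 (8 over the list alone), including the chemokine gene Pf4 (8.54 ± 1.11), with a median of 8.54, or 7.95 at the bound. Pf4 was also among the leading genes of macrophage-like clusters, so it does not mark platelets alone here. Of 10 B-cell genes 3 were higher (8 over the list alone), among them Cd22 (10.31 ± 2.18), and that list lost its call with an estimated correlation (adjusted p = 0.102). Macrophage fusion genes were higher for 3 of 10 (5 over the list alone), with Tyrobp, a myeloid signalling adaptor, at 8.96 ± 0.98. Among genes that met the naming rule, the largest difference was that of Krt19, an epithelial keratin (13.35 ± 3.15, adjusted p = 0.0103, 5 of 5 samples), a call that ended without replicate 3 or 5. F13a1, coagulation factor XIII (12.29 ± 2.21), Rbm47 (11.08 ± 1.70) and Esam, with 2 counts in CTC and a ratio of pooled counts of 9432 (counting interval 2611 to 77886), were also among the largest.

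Melanocyte genes did not separate DP from CTC, apart from Ednrb. Pmel (-1.21 ± 0.88, adjusted p = 1), Tyrp1 (-0.94 ± 0.66, adjusted p = 0.969) and Dct (-0.82 ± 0.73, adjusted p = 1) were each lower in DP in 4 of 5 samples and did not pass. The list median was -0.98 (camera adjusted p = 9.82e-05 downwards, and adjusted p = 0.257 with an estimated correlation). Ednrb, the endothelin receptor B gene, was higher in DP by 10.23 ± 1.92 (adjusted p = 0.00121), and it was also higher in WBC than in CTC. Proliferation genes passed for 0 of 19 (0 over the list alone, median 0.14), with Mki67 at 0.90 ± 1.04. The median log2 difference of all genes was 0.21 with TMM scaling, 0.10 with DESeq2 size factors and 0.13 with TMMwsp. The count of 737 genes was 361 without replicate 3, 367 without replicate 5, 336 in blood cells alone and 80 in lung cells alone, and 160 with sums of at least 5 cells. In lung and blood the DP sums of this comparison held 40.7% and 73.3% melanoma-like cells.

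CTC and WBC of the same samples served as the reference contrast. Melanocyte genes were higher in CTC for 14 of 16 members and lower for 1, Ednrb (15 and 1 over the list alone), with Tyrp1 at 7.09 ± 0.82 (adjusted p = 8.58e-07) and Pmel at 7.23 ± 1.15 (adjusted p = 5.46e-05), each higher in 5 of 5 samples, and a median of 7.01 (camera adjusted p = 2.57e-05, and adjusted p = 0.213 with an estimated correlation). All 16 pan-leukocyte genes (median -11.70) and all 17 monocyte and macrophage genes (median -12.12) were lower, the same numbers as over the list alone, and both lists passed with an estimated correlation at adjusted p = 0.00539. Ptprc differed by -12.49 ± 1.19 (adjusted p = 6.42e-08), Lyz2 by -12.56 ± 1.39 and Cd74 by -12.20 ± 1.22, each lower in 5 of 5 samples. Neutrophil genes were lower for 9 of 11 (10 over the list alone), among them S100a8, a calcium-binding protein of granulocytes (-11.52 ± 2.51). Outside the lists, Padi4, which encodes a histone deiminase, was lower by -13.89 ± 1.96. The class I MHC gene H2-D1 was lower by -5.14 ± 0.61, and 9 of 11 members of its list were lower (9 over the list alone). In CTC, the tetraspanin gene Tspan12 (8.55 ± 1.27) was among the largest increases. The median log2 difference of all genes was 0.74, or 0.63 and 0.86 with the other scalings, and 0.05 without the replicate block, where 1826 genes were higher and 1812 lower. In all, 3347 of 12595 genes passed, 2010 higher and 1337 lower in CTC, with 1281 for sums of at least 5 cells and 101 in lung cells alone.

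**Figure D3:**
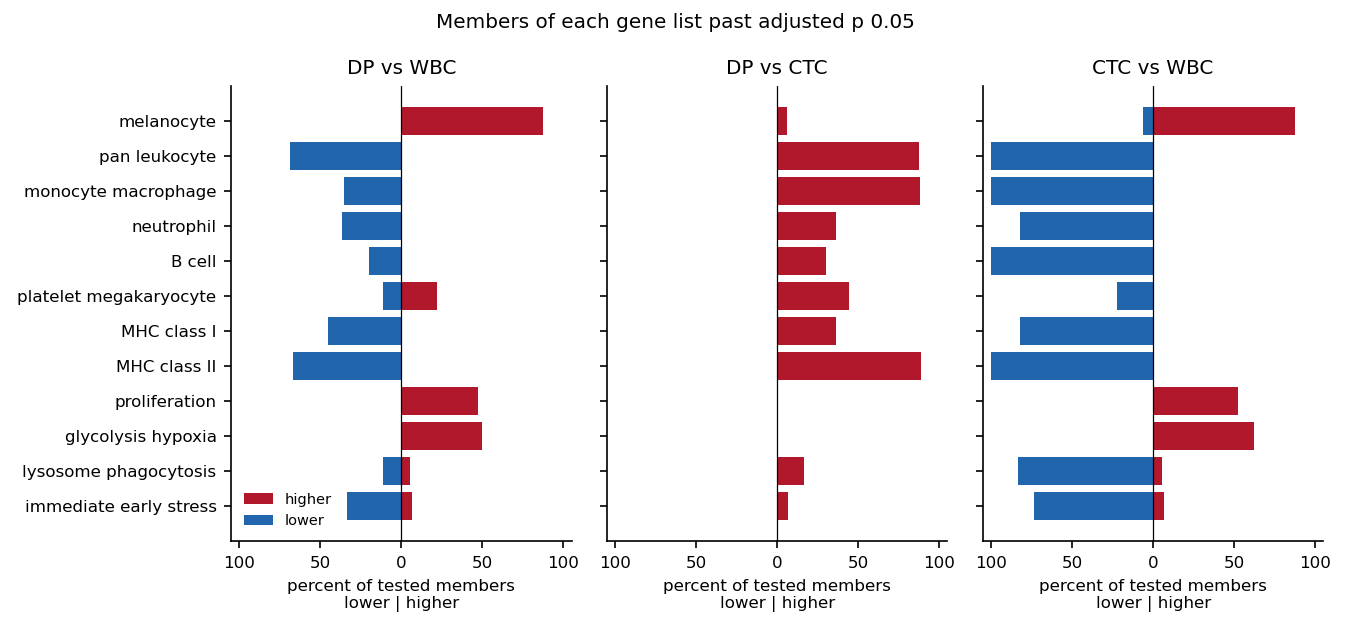
Percent of the tested members of each gene list that were higher (red, right) or lower (blue, left) at an adjusted p under 0.05, for DP against WBC, DP against CTC and CTC against WBC. Of 16 pan-leukocyte genes 11 are lower, 14 higher and 16 lower in the respective panels.

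To separate the mixture of branches from differences within cells, melanoma-like DP cells alone were compared with melanoma-like CTC, a comparison added after the data were seen. The class II MHC genes stood out. H2-Aa averaged 98.2 ± 83.6 CPM (n = 8) in DP and 0.735 ± 0.942 (n = 5) in CTC, a log2 difference of 8.19 ± 0.78 (adjusted p = 0.00421, edgeR's quasi-likelihood test), and was higher in 5 of 5 samples. H2-Ab1 (8.15 ± 0.88, adjusted p = 0.00562), H2-Eb1 (7.30 ± 0.87, adjusted p = 0.0104) and Cd74 (6.85 ± 0.69, adjusted p = 0.00421) were the other genes that passed, each higher in 5 of 5 samples. Over the list alone all 9 class II genes passed, and the list's median of 7.30 kept its call with an estimated correlation (adjusted p = 0.0336). Pan-leukocyte genes passed for 0 of 16 over all genes and 11 over the list alone (median 4.97, camera adjusted p = 7.02e-15, and adjusted p = 0.113 with an estimated correlation), with Ptprc at 5.77 ± 1.57 (adjusted p = 0.389). B-cell genes passed for 0 of 10 over all genes and 7 over the list alone (adjusted p = 0.19 for the list with an estimated correlation). Melanocyte genes had a median of 0.14, with Pmel at 0.03 ± 0.14 and Tyrp1 at 0.09 ± 0.15, and the proliferation list did not pass (camera adjusted p = 0.151). Of 11856 genes, 711 had an unadjusted p under 0.05, 4 passed, 54 passed without the sample block and 1003 passed with DESeq2. Without replicate 5, 0 genes passed (621 at an unadjusted p under 0.05).

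High class II levels were found in a minority of melanoma-like DP cells. In 39 of 272 (14.3%, exact interval 10.4 to 19.1) the class II list exceeded the highest CTC cell, which had 94.1 CPM, while the median DP cell had 3.25 CPM. Of the 272 cells, 20 exceeded the highest CTC cell for monocyte and macrophage genes and 22 for B-cell genes, and 50 (18.4%, exact interval 13.96 to 23.51) did so for at least 1 of these 3 lists. Of the 39 class II cells, 16 were also above for B-cell genes, 13 for monocyte and macrophage genes and 12 for neither. The same threshold was exceeded by 10 of 18 CDP and 14 of 24 Duplike control cells, all melanoma-like, and by 0 of 24 PltLike and 0 of 22 B16F10 cells, with exact upper limits of 14.2% and 15.4%.

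DP cells of the other branch were compared with WBC in the same way, also after the data were seen. No gene of 9834 passed with edgeR, although 776 had an unadjusted p under 0.05 and DESeq2 called 1880. Melanocyte genes had a median of 0.70, and 0 of 16 passed over all genes or over the list alone. Pmel averaged 80.7 ± 108 CPM (n = 9) in these DP cells and 28.6 ± 39.0 (n = 6) in WBC (1.27 ± 1.00, adjusted p = 0.816, higher in 6 of 6 samples), and Tyrp1 112 ± 95.01 against 44.5 ± 68.97 (1.48 ± 0.93, adjusted p = 0.737, 5 of 6). Ptprc was close in both (-0.26 ± 0.58, adjusted p = 0.957), and Mrc1, the macrophage mannose receptor, differed by 3.83 ± 1.11 (adjusted p = 0.357). The 2 groups differed in their clusters: of 46 WBC, 21 lay in the C1qb and C1qc clusters, 9 in the B-cell-like, 12 in the unnamed, 2 in the alveolar macrophage-like and 2 in the Spp1 cluster, against 85, 4, 14, 48 and 27 of 178 DP cells, so these differences also carry that of cell types. The pan-leukocyte list lay lower than other genes (median -0.44, camera adjusted p = 0.000134, and adjusted p = 0.288 with an estimated correlation). Single DP cells of this branch varied widely in Pmel, with medians of 7.85 CPM in lung and 19.8 CPM in blood. Their maxima were 7921 and 2349 CPM, against maxima of 1170 and 513 CPM in WBC. The 1 CTC in this branch had 3538 CPM, so the branch was not made up of leukocytes alone.

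Within DP, lung was compared with blood to see whether the class differed between the sites. A single gene passed of 12306, Ch25h, which encodes the enzyme that makes 25-hydroxycholesterol, at 112 ± 180 CPM (n = 7) in lung and 0.724 ± 1.90 (n = 7) in blood. It was higher by 13.80 ± 1.03 on the log2 scale (adjusted p = 0.0134, edgeR's quasi-likelihood test) in 5 of 5 samples. That estimate is far larger than the ratio of the means. The SD in blood exceeded its mean, so most blood sums held almost no Ch25h, and the size of the difference is uncertain. Gpx3 (7.93 ± 0.86) and the alveolar macrophage gene Plet1 (16.36 ± 1.82) had the next smallest p and did not pass (adjusted p = 0.0853 for each). Over the list alone, 7 of 9 alveolar macrophage genes (median 8.35), 14 of 18 lysosome genes (median 2.29) and 10 of 15 immediate-early genes (median 2.92), such as Fosb (5.51 ± 0.82), were higher in lung, as were 3 of 9 fibroblast genes, the list with the largest median (11.01), while 6 of 10 B-cell genes were lower (median -7.09), although 0 passed over all genes. These 5 lists passed camera with the preset correlation (adjusted p from 1.87e-12 to 0.000282) and none did with an estimated one (adjusted p from 0.29 to 0.316). Fibroblast genes took far more of the DP counts in lung than in blood in replicates 1 (1.83% against 0.0120%) and 2 (1.27% against 0.0171%). The difference was small in replicates 5 (0.0488% against 0.0220%) and 7 (0.0161% against 0.0119%), and reversed in replicate 3 (0.00068% against 0.0207%). Melanocyte genes had a median of -3.77 (adjusted p = 0.000756, and 0.47 as the adjusted p with an estimated correlation), with Tyrp1 at -3.33 ± 1.11 (adjusted p = 0.639), and the share of melanoma-like cells moved with them. An unadjusted p under 0.05 was found for 944 genes, DESeq2 called 3318, and 213 passed without the sample block. Leaving out replicate 7, whose melanoma-like share was higher in lung, gave 144 genes, and leaving out replicate 1, 2, 3 or 5 ended the call of Ch25h.

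As a direct reading of both programmes, melanocyte genes took 2.11% ± 1.36 (SD, n = 6) of the counts of DP and 0.0721% ± 0.0348 of those of WBC of the same samples, and were higher in 5 of 6 (exact two-sided sign-flip permutation p = 0.0625). Against CTC of the same samples the share was 2.52% ± 1.01 in DP and 3.25% ± 1.27 in CTC (n = 5), higher in DP in 1 of 5 (exact p = 0.125). Pan-leukocyte genes took 0.409% ± 0.296 of DP counts and 1.302% ± 0.186 of WBC counts, lower in 6 of 6 samples (exact p = 0.03125, the smallest that 6 samples allow), and 0.306% ± 0.172 against 0.0985% ± 0.0241 in CTC, higher in 5 of 5 (exact p = 0.0625, the smallest that 5 samples allow). With any of the 6 samples left out, or in blood cells alone, the exact test of DP and WBC could reach no less than p = 0.0625. With every cell thinned to 10000 counts, at least 2 melanocyte and 4 pan-leukocyte genes were detected together in 131 of 450 DP cells (29.1%, exact interval 24.95 to 33.55), in 0 of 43 CTC (exact upper limit 8.22%) and in 28 of 46 WBC (60.9%, 45.4 to 74.9). Unthinned, the shares were 96.7%, 100% and 100%, so depth alone saturates this measure. Melanoma-like DP cells had both in 23 of 200 from blood and 8 of 72 from lung, and DP cells of the other branch in 68.5% of those from blood and 47.6% of those from lung. Ednrb alone made up 59.1% of the melanocyte-list counts of WBC and had 0.0645 CPM in CTC, and detection without it was not tested. Between samples the DP and CTC difference was 27.1 points (5 of 5 samples, exact p = 0.0625) and the DP and WBC difference -30.8 points (exact p = 0.125).

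**Figure D4:**
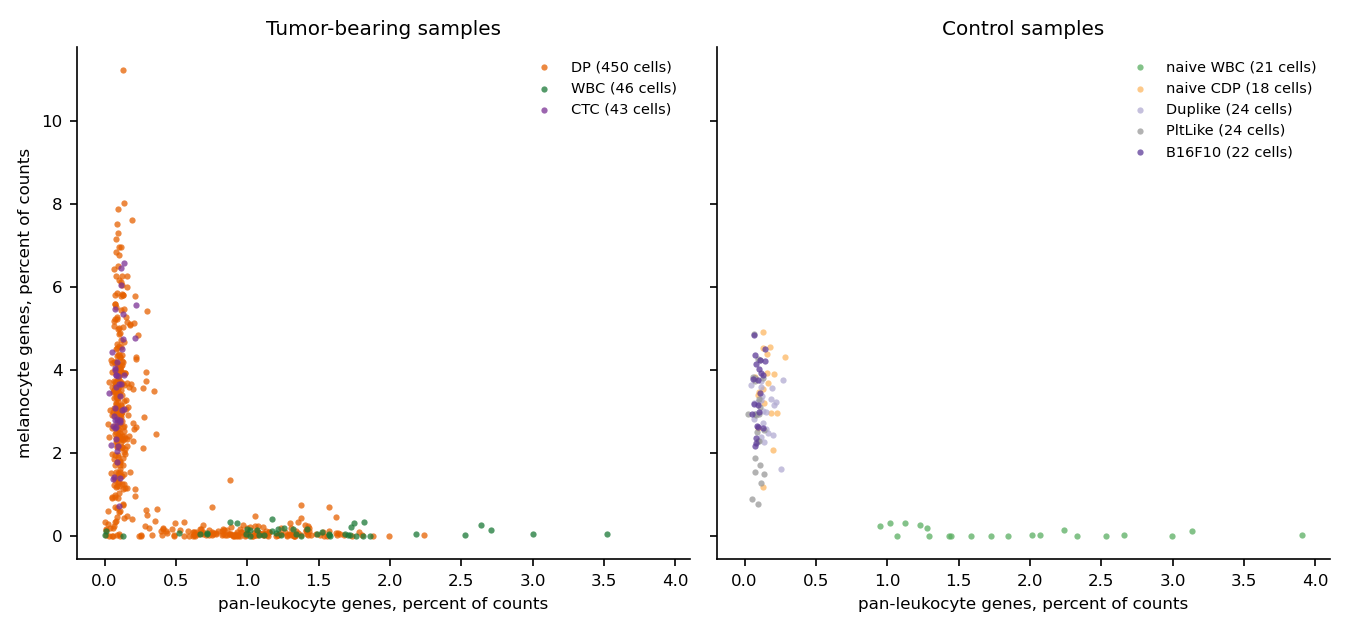
Percent of counts in melanocyte genes (vertical) against percent in pan-leukocyte genes (horizontal), 1 point per cell, tumor-bearing samples on the left and controls on the right. The 450 DP cells lie along both axes, with the 43 CTC on one and the 46 WBC on the other.

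Each control was 1 sample, so batch and group could not be told apart, and the lone sample was assumed to vary like the others in each test. All 18 CDP cells were melanoma-like, against 60.4% of DP cells. The DP and CDP comparison over all cells therefore set a mixture against melanoma-like cells, and few passing genes there do not show similarity. Against B16F10 cells, proliferation genes stood higher in CTC as a list. These genes took 0.0486% of counts in the B16F10 cells but 0.832% in PltLike cells, also melanoma-like, which is above the mean of CTC. The direction of the difference therefore depended on the control, and PltLike was not tested. Mki67 averaged 120 ± 42.3 CPM (n = 5) in CTC and had 0 counts in the B16F10 cells (adjusted p = 0.054, not past), and Pclaf, a replication factor, was at least 13706-fold higher (116 ± 26.9 CPM, adjusted p = 0.0243), as was Capn6 at least 10350-fold (adjusted p = 0.0236). The proliferation list had 0 of 19 genes past over all genes and 7 over the list alone (median 4.32, camera adjusted p = 1.23e-31, and adjusted p = 0.0151 with an estimated correlation). Pltp, phospholipid transfer protein, was lower by -9.42 ± 1.19 (0.061 ± 0.053 against 40.1 CPM, adjusted p = 0.000961). In all, 6 of 16423 genes passed, 4 higher and 2 lower, with 1 past without replicate 1, 2 without replicate 3, 3 without replicate 6, 559 with DESeq2 and 329 in melanoma-like cells alone. Leaving out replicate 1, 3 or 6 ended the calls of Pclaf and Capn6.

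Between DP and naive CDP, 0 of 16423 genes passed with edgeR, 386 had an unadjusted p under 0.05, and DESeq2 called 750. Capn6 came nearest, with 0 counts in CDP and at least 8724-fold more in DP (80.8 ± 35.4 CPM, n = 9, adjusted p = 0.0587). Proliferation genes were higher in DP in 3 of 19 members over the list alone (median 4.66, camera adjusted p = 9.88e-19, and adjusted p = 0.127 with an estimated correlation), with Mki67 at 137 ± 50.3 against 5.41 CPM. Neutrophil genes were lower in 3 of 13 over the list alone (median -3.48, camera adjusted p = 2.73e-06, and adjusted p = 0.406 with an estimated correlation). In melanoma-like cells alone 442 genes passed, and without replicate 2 or 4, 3 and 1 did.

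WBC of tumor-bearing samples differed from naive WBC in 253 of 16423 genes, 137 higher and 116 lower. Mcm5, a replication helicase subunit, had 0 counts in naive WBC and was at least 1312-fold higher (adjusted p = 0.0278), and Mcm2 was higher by 8.09 ± 1.91 (75.9 ± 74.1 CPM, n = 6, against 0.278, adjusted p = 0.0292). Proliferation genes were higher for 3 of 19 (15 over the list alone), with a median of 8.52, or 8.02 at the bound (camera adjusted p = 1.95e-09, and adjusted p = 0.912 with an estimated correlation), and glycolysis genes for 1 of 16 (7 over the list alone), Tpi1 at 4.23 ± 0.98 (list adjusted p = 0.0187, and adjusted p = 0.912 with an estimated correlation). The median log2 difference of all genes was 1.33. Fcer2a, the low-affinity IgE receptor of B cells, was lower by -13.34 ± 2.68 (0.044 ± 0.083 against 441 CPM, adjusted p = 0.0103), Ighmbp2 by -10.60 ± 1.496 (adjusted p = 0.000351) and the melanosome gene Gpr143 by -6.50 ± 1.26. Single WBC sums carried some lists of cell types. Fibroblast genes took 2.62% of WBC counts in lung of replicate 2 and at most 0.00102% in any other WBC sum. T-cell genes took 0.132% in blood of replicate 3 and at most 0.0149% in any other. Lung epithelial genes took 3.63% in lung of replicate 5 and at most 0.163% in any other, so the WBC class did not hold leukocyte RNA alone. Lists of cell types had medians at the bound of 9.82 for fibroblast, 8.55 for alveolar macrophage, 7.002 for T-cell, 2.13 for dendritic-cell and 1.48 for lung epithelial genes, 0 for NK-cell, platelet, erythroid and endothelial genes, -1.12 for B-cell and -1.44 for neutrophil genes. Among these 11 lists 1 member passed, a platelet gene that was lower, and the 46 WBC of tumor-bearing samples included 18 from lung. The median cell of naive WBC held 1.05 Mcounts against 4.93 Mcounts, so low genes were less detectable there. Without replicate 2 the count was 414, and DESeq2 called 3347.

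The Duplike and PltLike controls were not tested. Duplike cells had 6351 CPM of Pmel and 40.9 CPM of Ptprc, with Cd74 at 554 CPM and Lyz2 at 943 CPM. PltLike cells had 6152 CPM of Pmel but 0.028 CPM of Ptprc, 0.473 CPM of Cd74 and 0.884 CPM of Pf4. In DP summed over tissues Ptprc averaged 153 ± 183 CPM (n = 9) and ranged from 20.2 to 582 CPM.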

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

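Groups of 4 to 10 samples were searched for a sample far from the rest by Dixon's criterion, which picks about 1 in 20 groups by chance: 12 of 136 groups had one, where 6.8 were expected. The percent of DP cells in the melanoma-like branch, lung minus blood, was 48.4 in replicate 7 and -90.9 to -59.1 in the others (replicates 1, 2, 3 and 5). Replicates 8 and 9, labelled P like replicate 7, held DP of 1 tissue each, with 91.4% in lung and 44.8% in blood. Neither could therefore show or fail to show a reversal. The percent of melanoma-like DP cells with leukocyte genes above the highest CTC cell was 53.8 in replicate 2 and 8.89 to 23.1 in the others. In replicate 4 the DP cells were 15 lung cells of the other branch and the 2 WBC came from blood, so the tissues differed. There the log2 difference of DP and WBC was 0.69 for Pmel (others 5.26 to 7.81), -0.18 for Mlana (4.68 to 7.42), 0.0365 for Slc45a2 (5.52 to 7.71) and 0.74 for Il17rc (4.39 to 5.40). In replicate 6 the log2 difference was 1.83 for Itgax between DP and CTC (others 6.00 to 7.01). These differences within single samples are not the edgeR estimates given earlier, which were larger for Il17rc and Itgax, so the sizes should not be compared. As log2(CPM + 1), Capn6 was 3.35 in DP of replicate 4 (others 5.68 to 7.002) and Ly6g was 0.0068 in DP of replicate 2 (0 to 0.0017). In WBC of replicate 5, Fcer2a was 0.27 (0 to 0.085), Ighmbp2 0.53 (0 to 0.18) and Gpr143 0.50 (0.20 to 0.31). By an interaction term, the DP and WBC difference of Sec23b was larger in lung than in blood by 7.52 ± 1.22 (adjusted p = 0.0302, edgeR).

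For leukocyte genes in melanoma-like DP cells, the tests of RNA from other wells and of a leukocyte in the same well were written before their results, and that of a cell with both programmes after. If RNA came from 1 pool shared by wells, B-cell and monocyte genes should occur together, yet of the cells above the highest CTC cell for either 10.5% were above it for both (4 of 38). The cut-offs were unequal, at 11.8 CPM for B-cell and 344 CPM for monocyte genes. RNA of a pool could pass the lower one alone, as 18 cells did, while 16 passed the monocyte one alone. The test argues only against a pool that brings both above these cut-offs, and leaves RNA from a single leukocyte well open. A leukocyte in the same well should add detected genes, and the mean difference of 69.9 genes (4 of 8 samples higher, with 160 of 256 sign flips as large in an exact permutation test) could not tell. The melanocyte share of counts was lower in these cells by 0.629 points (7 of 8 samples, exact p = 0.09375). One cell holding both programmes could not be told from such a pair, because both would give the same RNA. Of Duplike control cells 58.3% also lay above the highest CTC cell, but the labels do not say what these cells are, so they could not decide.

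For the lower share of melanoma-like DP cells in lung, the test of sequencing depth was written before its result and the other two after. Thinning every cell to 10000 counts moved 0.222% of DP cells to the other branch, which argues against depth. If the other-branch DP cells were leukocytes sorted as DP, their melanocyte share should be close to that of WBC, and it was a median of 2.67% of that of melanoma-like DP cells (range 0.277 to 4.26) and 0.0158 points above WBC (4 of 5 samples higher, exact p = 0.5, smallest possible 0.0625). Ednrb made up 59.1% of the melanocyte-list counts of WBC and had 0.0645 CPM in CTC, so the comparison with WBC weighs tumor genes little. Pmel and Tyrp1 had higher means in these DP cells than in WBC and did not pass, while the median single cell held less Pmel in DP than in WBC in either tissue. These values leave leukocytes sorted as DP open without showing that the shares were equal, and the branches were drawn from expression. An effect of the tissue itself could not be told apart from the sort, with a lower share in 4 of 5 samples, and the exception carried a P label.

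For melanocyte reads in WBC, both tests were chosen after the result was seen. Carry-over from wells of melanoma cells should bring all genes in proportion, and over 13 genes the SD of log2(WBC / CTC) was 2.13, which argues against 1 such source for all of them. That spread rests on Mitf at 23.3% and Syngr1 at 7.78% of their CTC level, while the other 11 genes lay at 0.198% to 1.13%, so carry-over of those 11 was left open. For tumor RNA taken up in the animal, the share of these genes was 0.0104% in naive WBC and 0.00527% to 0.0717% in the tumor-bearing samples, so with 1 naive sample it could not be told.

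Splits of the labels within samples, with predictions written before their results, tested whether the counts of genes could arise by chance. In 4 comparisons only the real split of 21 gave as many genes. These were DP and WBC (2586, highest other 9) and DP and CTC (737, highest other 2). The others were CTC and WBC (3347, highest other 2178) and melanoma-like DP and CTC (4, highest other 1). A share of 1 of 21 lies just under 0.05 and is the smallest that 21 splits can give. It argues against chance at that level and does not exclude it. For DP and WBC of the other branch the real count was 0 (highest other 0), so 21 of 21 splits had as many genes and the splits could decide nothing. For DP of lung and blood 16 splits could not reach 0.05 (real 1, highest other 2, 3 as large).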

How the results depend on the processing

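The results rest on few samples, and genes that passed with edgeR and the sample as replicate block were fewer than with DESeq2. With DESeq2, 5545 genes passed for DP and WBC, 1570 for DP and CTC, 6032 for CTC and WBC, 3318 for lung and blood, 750 for DP and CDP, 559 for CTC and B16F10, 3347 for WBC and naive WBC, 1003 for melanoma-like DP and CTC and 1880 for the other branch. With sums of at least 5 cells the first 3 counts were 294, 160 and 1281, with cells weighted equally 5514, 292 and 6311, and in lung cells alone 0, 80 and 101, where fewer sums were left. In blood cells alone DP and CTC gave 336. For lung and blood, DESeq2 size factors gave 3, no filter on low counts 6, equal weights 17 and no replicate block 213, and for melanoma-like DP and CTC no replicate block gave 54. In melanoma-like cells alone DP and CDP gave 442 and CTC and B16F10 329. In lung cells alone the estimates of 4 genes changed sign between DP and WBC: Lyz2 0.24, Adgre1 0.0472, Zbtb46 -1.07 and Eno1 -0.13. None differed there (edgeR adjusted p from 0.905 to 0.997). The cause was not tested.

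Gene lists past camera fell from the preset to an estimated correlation: 15 to 4 for DP and WBC, 18 to 8 for DP and CTC, 19 to 11 for CTC and WBC, 9 to 1 for melanoma-like DP and CTC, 19 to 0 for lung and blood (3 with fry), 8 to 0 for DP and CDP (0 with fry), 6 to 1 for CTC and B16F10 (0 with fry), 5 to 0 for WBC and naive WBC (0 with fry) and 8 to 0 for the other branch (0 with fry). For the differences of lung against blood they fell from 10 to 0 for DP and WBC (1 with fry) and from 13 to 0 for DP and CTC (0 with fry). The melanocyte share of DP minus that of WBC was 1.61 points as a mean over cells (exact sign-flip p = 0.03125). That of DP minus CTC was 0.228 points in blood cells alone (exact sign-flip p = 0.5625), the opposite sign to that over both tissues. The pan-leukocyte difference of DP and WBC in blood cells alone was -1.18 (exact p = 0.0625). Detection of both programmes differed by -19.6 points between DP and WBC at 5 counts per gene unthinned (exact p = 0.03125), and unthinned by -3.22 between DP and CTC and by 0 between CTC and WBC.

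With each sample left out in turn, the counts ranged from 1599 to 2580 for DP and WBC, 361 to 725 for DP and CTC, 2386 to 3340 for CTC and WBC, 0 to 144 for lung and blood, 0 to 3 for DP and CDP, 1 to 8 for CTC and B16F10, 200 to 414 for WBC and naive WBC, 0 to 4 for melanoma-like DP and CTC and 0 to 1 for the other branch. The melanocyte share differences ranged from 1.70 to 2.45, -0.931 to -0.544 and 2.87 to 3.58 in the order DP and WBC, DP and CTC, CTC and WBC, the pan-leukocyte ones from -0.950 to -0.814, 0.138 to 0.245 and -1.21 to -1.11, detection of both from -39.3 to -19.0, 23.4 to 31.4 and -73.4 to -55.9, and the melanoma-like share from -79.6 to -44.8. Among the counts, lists and shares above, leaving aside single genes, 230 values under an alternative stayed the same, 63 moved, 2 were stronger and 7 weaker. Single genes were less stable: of the named genes that passed, 16 of 65 kept their call under every alternative for DP and CTC, 24 of 115 for CTC and WBC and 0 of 95 for DP and WBC, where lung cells alone gave 0 genes.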

Other observations

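Among melanoma-like DP cells, platelet and megakaryocyte genes exceeded the highest CTC cell (102 CPM) in 32 of 200 cells from blood (exact interval 11.2% to 21.8%) and in 5 of 72 from lung (6.94%, 2.29 to 15.5), against 1 of 18 CDP, 2 of 24 Duplike, 1 of 24 PltLike and 0 of 22 B16F10 cells. Neutrophil genes did so in 14 of 272 DP cells and in 13 of 18 CDP cells. Proliferation genes took 0.454% ± 0.121 of counts in CTC and 0.398% ± 0.118 in DP, 0.726% in Duplike and 0.832% in PltLike, but 0.0486% in B16F10 and 0.0519% in CDP cells. These controls, with 22 B16F10 and 17 of 18 CDP cells, lay together in a cluster that held 3 DP cells. A cluster of 96 cells with Car9 and Bnip3, both induced by low oxygen, held 71 DP cells from blood, 11 from lung and 14 CTC. Ednrb averaged 853 ± 526 CPM (n = 6) in WBC and 0.072 ± 0.046 (n = 5) in CTC. No hypothesis beyond the tests above was examined.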
